A study of Mus musculus and Rattus norvegicus with 33 samples.

How the data were processed

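RNA sequencing of the tibialis anterior, a muscle at the front of the shin that lifts the foot, gave 33 libraries from wild-type animals, 17 from mice and 16 from rats. Per the labels' protocols, stimulators were implanted and programmed over Bluetooth to train the animals, total RNA was extracted with Trizol and RNeasy columns, and libraries were made with an Illumina kit. Left legs were stimulated or sham-operated, and right legs of the same animals were the contralateral controls. Legs are named by the codes in their labels, TAL for a left and TAR for a right leg, each with the animal number, and a mouse or rat is named by its left leg. The label of the sham legs gives surgery and not whether a device was implanted. Trained legs were labelled as taken 1 hour after exercise, and no time was given for contralateral or sham legs. Groups were taken from the labels. Mice were trained for 2 days (n = 2), 10 days (n = 3) or over 17 days (n = 3), and 9 contralateral mouse legs were used, with 1 of them, leg TAR348, from an animal whose left leg was not analysed here. Rats were trained daily for 30 days (n = 2) or every 3 days for 30 days (n = 3) or sham-operated (n = 3), and each of these 8 rats gave a contralateral leg. No mouse leg was labelled as sham-operated. In mice, implant surgery and the side of the body can therefore not be told apart from training.

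The authors deposited CPM, counts scaled to each library's total, with 0.0001 added to each value, and that offset was subtracted. After this every column summed to 1000000. The submitters' processing notes name STAR 2.7.8a, Partek, DESeq2 and the builds mm10, GRCm39 and rn7, without giving the role of each. Which of these steps made the deposited CPM is not given in the sources used here. The mouse table held 21345 genes with coordinates. Of 21295 genes also found in a GRCm38 annotation 2.2 percent had the same start, so mouse coordinates are given as GRCm39, and rat coordinates as rn7, in both cases as deposited. In mice 23 entries that shared a symbol with a more abundant entry were left out. The rat table held 13166 transcript models, which were summed to 12411 gene symbols, 492 of them with more than 1 model.

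The smallest steps between low CPM values gave an estimated depth of 26.5 to 43.1 M reads per mouse library (median 33.8). In rats it was 4.9 M in contralateral leg TAR299 and 11.6 to 28.0 M in the other libraries. Whole reads were not recovered. Of the values worth up to 20 reads, 85.3 to 87.2 percent in mice and 87.4 to 89.2 percent in rats were whole multiples of a step at a tolerance of 0.05, under the 95 percent needed, so no test of counts was run. Reads of near-identical copies, such as Amd1, Amd2 and Amd-ps3, Hspa1a and Hspa1b or the myosin heavy chain genes, could be divided between the copies by the counting, and their separate values are uncertain.

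Genes with a CPM of 1 or more in at least 2 libraries were tested, 13657 in mice and 10356 in rats, on log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3 (moderated linear models with a mean-variance trend, 2-sided). All groups of a species shared the estimate of the spread. Adjusted p-values are Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes. Errors of fold changes are standard errors and errors of CPM are standard deviations. The p-values treat each leg as a separate sample. There were 12 comparisons, 6 in each species. Other steps used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

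The animal numbers pair the samples, since a left and a right leg with the same number came from the same animal. Own-leg deviations from the group means correlated across genes at 0.12 to 0.30 in the mice, apart from mouse TAL345 at -0.03, and at 0.04 to 0.26 in the rats. The fit was made without this pairing, and a fit with the animal as a block was the alternative. A value from the blocked fit is called the paired value in the text. Between 2 groups of left legs, which share no animal, the paired value is a difference of own-leg changes. There it is not the same quantity as the unpaired value.

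Gene lists were fixed for immediate early genes, stretch and load response, heat shock and chaperones, extracellular matrix, fast glycolytic fibre, slow and oxidative fibre, oxidative phosphorylation, TCA cycle and fatty acid oxidation, PGC-1 and exercise metabolism, cytoplasmic ribosomal proteins, ribosome biogenesis, denervation markers, regenerating and developing fibre, satellite cells, proliferation, atrophy and autophagy, ATF4 and amino acid response, circadian clock and inflammatory cytokines, and for markers of macrophages, neutrophils, lymphocytes, endothelium, smooth muscle and pericytes, fibroblasts and fibro-adipogenic cells, tendon, adipocytes, Schwann cells and nerve, and erythroid cells. Lists with at least 5 tested members were tested, which was 28 lists and 330 tests. Lymphocyte markers fell short of that in both species and neutrophil markers in rats. Of the tested proliferation genes 2 of 11 in mice and 3 of 12 in rats had a mean of 1 CPM or more in contralateral legs. Of the inflammatory cytokines 8 of 13 and 6 of 10 did. The other members were low there and could pass the filter through the stimulated legs, so a rise of these lists may be partly built in. Each list was compared with all other genes by camera in limma with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 330 tests. A list is said to have risen or fallen where that test was passed. The test was repeated with an estimated correlation and with the animal as a block. Fry, which asks whether the genes of a list move on balance in one direction and does not compare them with other genes, was run as well. With an estimated correlation 2 of the 130 list calls held, both of immediate early genes in rats trained every 3 days. An own-leg median is the median over a list of the log2 change from an animal's contralateral to its left leg. Some lists share genes, so their results are not independent. Myog and Ncam1 are in both the denervation and the regenerating fibre lists, and Col15a1, Lum and Dcn in both the matrix and the fibroblast lists.

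Genes are named by a rule. For each comparison with contralateral legs these are the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM in either group and the same direction in every animal. For each called list they are up to 4 called members with the smallest p, between trained groups the 5 largest rises and falls, and in every comparison 20 fixed genes. Called genes named from a comparison with contralateral legs moved in the same direction in every animal of the trained group unless stated otherwise. Genes outside the rule are said to have been chosen after their values were seen.

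The alternatives were a pseudocount of 2, no filter on low values, median-of-ratios rescaling of the CPM, only the 2 groups compared in the fit, the animal as a block or as a random effect, and leaving out each library in turn. Further alternatives were chosen after seeing the data. In these the rat transcript models were not summed, rat ribosomal RNA (2.1 to 8.21 percent of the CPM) was left out, 15 mouse mitochondrial genes and 11 nuclear copies were left out, or each library in turn was left out of the list tests. The block and the left-out libraries were also run, after their values were seen, on the polyamine genes and Ighm. The fits were tested on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold. Against contralateral legs they recovered 66 percent of the 2-fold changes after 2 days, 82 percent after 10 days and 83 percent after over 17 days in mice. In rats they recovered 67 percent for daily training, 73 percent for training every 3 days and 73 percent for sham surgery. Recovery was 60 percent for 10 against 2 days, 68 percent for over 17 against 10 days and 57 percent for over 17 against 2 days. It was 40 percent for daily against every 3 days, and 47 and 57 percent for these 2 groups against sham legs. Each gene was drawn independently, with no shift shared within a library or an animal, so such shifts are not covered.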

Results

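The series followed what repeated electrical stimulation of a leg nerve does to the muscle it drives, in mice over increasing lengths of training and in rats over 30 days at different frequencies. Expression was compared between the stimulated tibialis anterior and the muscle of unstimulated contralateral legs, between trained groups, and, in rats, with legs that had sham surgery. The mice had no sham group, so their changes against contralateral legs hold any effect of surgery or side as well as that of training. The 17 mouse libraries held an estimated 26.5 to 43.1 M reads and the 16 rat libraries 4.9 to 28 M, with the lowest value in rat contralateral leg TAR299. A median of 19188 mouse genes and 12516 rat transcript models were above 0 in a library. Mitochondrial genes took between 11.4 percent of the CPM, in the stimulated leg of 2-day mouse TAL344, and 25.4 percent, in that of mouse TAL349 of the longest training.

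**Figure D1:**
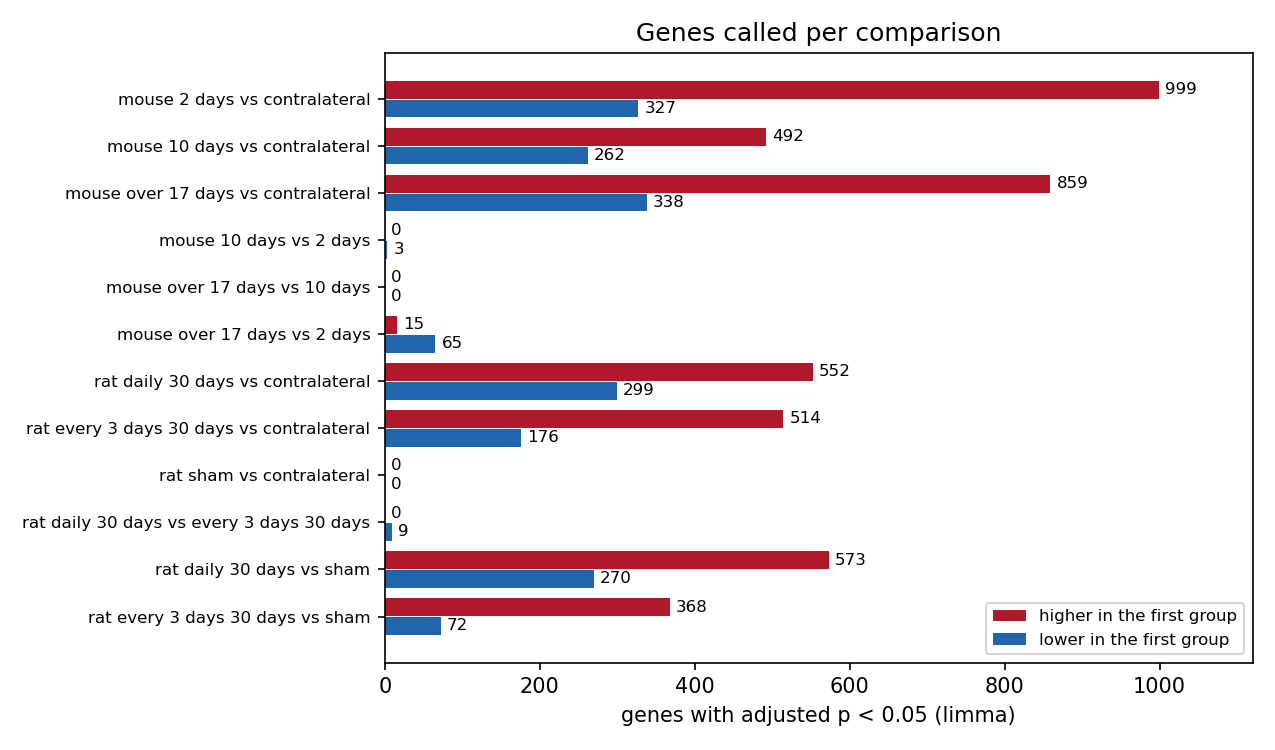
Number of genes called by limma (horizontal axis) in each of the 12 comparisons (vertical axis), with red bars for genes higher and blue bars for genes lower in the group named first. Every trained group had at least 690 called genes against contralateral legs, and the sham group had 0.

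After 2 days of training, immediate early genes, which cells switch on soon after a stimulus, and genes that respond to stretch and load rose in the stimulated mouse muscle (adjusted p = 0.191 and 0.0666 with an estimated correlation). Atf3, a stress-induced transcription factor (chromosome 1, 190902493 to 190950236), went from 7.45 ± 7.72 CPM (SD, n = 9) in contralateral legs to 388 ± 223 CPM (SD, n = 2), a log2 change of 5.96 ± 0.65 (limma adjusted p = 1.71e-05), with 5.34 without mouse TAL344 and 6.59 without mouse TAL345. Egr1, an early growth response transcription factor, rose from 7.21 ± 9.01 to 232 ± 7.86 CPM, and Fosb, a partner in the AP-1 transcription factor, rose by 5.37 ± 0.53 on the log2 scale. Among load genes, the muscle ankyrin repeat gene Ankrd1 rose from 34.6 ± 19.8 to 624 ± 109 CPM and Csrp3, a Z-disc protein that senses stretch, from 21.6 ± 8.19 to 483 ± 103 CPM. Small heat shock proteins of muscle also rose, with Hspb7 at 3.37 ± 0.31 and Cryab at 2.22 ± 0.25 on the log2 scale.

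By list, 18 of the 28 immediate early genes rose over all genes tested and 21 adjusted over the list alone, with a median log2 change of 1.94 and own-leg medians of 2.30 and 1.47 in the 2 mice (adjusted p = 0.191 with an estimated correlation). Of the 19 stretch and load genes 13 rose (16 adjusted over the list alone), with a median of 2.06 (adjusted p = 0.0666 with an estimated correlation). Heat shock and chaperone genes had 9 of 22 higher (10 adjusted over the list alone), a median of 0.38 and a mean of 0.97 (adjusted p = 0.548 with an estimated correlation). Extracellular matrix genes had a median of 1.18, with 6 of 28 higher and 21 adjusted over the list alone (adjusted p = 0.727 with an estimated correlation), and own-leg medians of 1.87 in mouse TAL344 and 0.66 in mouse TAL345. The macrophage markers had a median of 1.31, with 3 of 20 higher and 7 adjusted over the list alone (adjusted p = 0.8 with an estimated correlation) and own-leg medians of 2.35 and 0.81 in these mice, and Cd68, a lysosomal protein of macrophages, rose by 3.73 ± 0.58. Ribosome biogenesis genes rose with a median of 0.30, 5 of 28 higher and 10 adjusted over the list alone (adjusted p = 0.692 with an estimated correlation), and own-leg medians of 0.41 and 0.06. These 6 lists kept their call without any one library, but in the last 3 mouse TAL344 changed far more than mouse TAL345.

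A further group of lists lost the call without mouse TAL344. Among them, the lists of denervation markers and of regenerating and developing fibres share Myog and Ncam1. Ribosomal protein genes rose (16 of 41 higher, 33 adjusted over the list alone, median 0.59, adjusted p = 0.653 with an estimated correlation). Their own-leg medians were 0.96 in mouse TAL344 and 0.06 in mouse TAL345, and the adjusted p without mouse TAL344 was 0.349. Denervation markers, genes that muscle expresses after losing its nerve, rose (8 of 15 higher, 12 adjusted over the list alone, median 1.58, adjusted p = 0.548 with an estimated correlation) with own-leg medians of 3.29 and 0.34, and without mouse TAL344 the adjusted p was 0.225. Genes of regenerating and developing fibres rose (5 of 15 higher, 9 adjusted over the list alone, median 1.33, adjusted p = 0.692 with an estimated correlation), with own-leg medians of 2.30 and 0.01 and an adjusted p of 0.369 without mouse TAL344. The acetylcholine receptor subunit gene Chrna1 stood at a log2 change of 2.4 ± 0.73 (adjusted p = 0.0455, paired 0.103), at -0.09 without mouse TAL344 (0.986) and at 4.88 without mouse TAL345. Its call also ended without any one of contralateral legs TAR337, TAR340, TAR341, TAR342, TAR343, TAR345, TAR348 or TAR349, with adjusted p-values of 0.0513 to 0.065. Endothelial markers fell (0 of 15 higher and 1 lower, 0 adjusted over the list alone, median -0.42, adjusted p = 0.548 with an estimated correlation), and the adjusted p without mouse TAL344 was 0.344. Slow and oxidative fibre genes rose (4 of 18 higher, 5 adjusted over the list alone, median 0.52, adjusted p = 0.727 with an estimated correlation). Fast glycolytic genes fell (3 of 22 lower, 3 adjusted over the list alone, median -0.06, adjusted p = 0.807 with an estimated correlation). Without mouse TAL344 the adjusted p-values were 0.676 for slow and 0.097 for fast genes. The median of the fast genes was then -0.15, and their own-leg medians were alike, at -0.39 in mouse TAL344 and -0.36 in mouse TAL345.

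The lists called after 2 days also held proliferation genes (3 of 11 higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.91, adjusted p = 0.663 with an estimated correlation), whose adjusted p was 0.243 without mouse TAL345 and 0.0555 without contralateral leg TAR340. Of these proliferation genes 2 of 11 had a mean of 1 CPM or more in contralateral legs, so the filter could favour a rise. Smooth muscle and pericyte markers passed as lower with a median of -0.24, although 1 of the 14 members was called higher and 0 lower, also adjusted over the list alone (adjusted p = 0.8 with an estimated correlation). TCA cycle and fatty acid oxidation genes passed as lower with 1 of 22 lower, 0 adjusted over the list alone and a median of -0.05 (adjusted p = 0.879 with an estimated correlation). Schwann cell and nerve markers passed as lower with 0 of 12 called, also adjusted over the list alone, and a median of -0.20 (adjusted p = 0.807 with an estimated correlation and 0.0623 in the paired fit). The call of smooth muscle markers ended without mouse TAL344 (adjusted p = 0.898, median 0.05) and without contralateral legs TAR337, TAR340 or TAR345 (0.0547, 0.0517 and 0.0553). That of TCA cycle genes ended without mouse TAL345 (0.442) and without contralateral legs TAR342, TAR344 or TAR345 (0.0595, 0.0526 and 0.0654). That of Schwann cell markers ended without mouse TAL344 (0.721) and without contralateral legs TAR337, TAR344, TAR348 or TAR349 (0.055, 0.0561, 0.0535 and 0.091). In the paired fit tendon markers (adjusted p = 0.0384) and fibroblast markers (0.0335) passed as higher and oxidative phosphorylation genes (0.0109) as lower.

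In total 1326 of 13657 genes were called after 2 days, 999 higher (75.3 percent) and 327 lower, and 329 rose and 46 fell by at least 2-fold. The median of all genes moved by 0.113 on the log2 scale, and after median-of-ratios rescaling 53.1 percent of the called genes were higher (789 higher and 698 lower). With mitochondrial genes left out, which was chosen after seeing the data, the share was 62.6 percent. The count was 196 without mouse TAL344, 3421 without mouse TAL345 and 560 in the paired fit, and of the 69 called named genes 24 kept their call in every alternative and 44 lost it without mouse TAL344. The largest fall was in Odf3l2, a relative of a sperm tail protein gene (chromosome 10, 79475360 to 79481572), from 9.38 ± 3.44 to 0.38 ± 0.37 CPM.

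After 10 days of training immediate early genes were again among the largest rises of single genes in mice, but their list call did not hold with an estimated correlation. Fosb (chromosome 7, 19036621 to 19043976) went from 0.73 ± 1.36 CPM (SD, n = 9) to 69.8 ± 16.2 CPM (SD, n = 3), a log2 change of 6.20 ± 0.45 (limma adjusted p = 3.31e-07). Nr4a3, a nuclear receptor induced by exercise, rose by 4.92 ± 0.52 (paired 5.62), and Irs2, an adaptor of the insulin receptor (chromosome 8, 11034681 to 11058458), from 23.1 ± 6.02 to 210 ± 31.4 CPM. Trim63, a ubiquitin ligase of muscle protein breakdown also called MuRF1, rose by 1.96 ± 0.21 and Xirp1, an actin-binding protein of damaged or loaded muscle, by 3.32 ± 0.26. Ighm, the constant region of the IgM heavy chain (chromosome 12, 113382178 to 113386350), dropped from 54.8 ± 14.3 to 6.88 ± 0.76 CPM, with a log2 change of -2.87 ± 0.22.

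Immediate early genes rose after 10 days (17 of 28 higher, 22 adjusted over the list alone, median 1.39, adjusted p = 0.107 with an estimated correlation). So did stretch and load genes (12 of 19 higher, 16 adjusted over the list alone, median 0.95, adjusted p = 0.0573 with an estimated correlation). Extracellular matrix genes rose with a median of 1.16, 10 of 28 higher and 26 adjusted over the list alone (adjusted p = 0.507 with an estimated correlation), and Col3a1, a fibrillar collagen, rose by 2.58 ± 0.48. The collagen gene Col1a1 stood at 2.10 ± 0.55 (adjusted p = 0.0283) and lost its call without mouse TAL340 (1.42, adjusted p = 0.211) or TAL341 (0.0538). Macrophage markers had a median of 1.22 with 1 of 20 higher and 9 adjusted over the list alone (adjusted p = 0.653 with an estimated correlation). Fibroblast markers had a median of 0.60 with 2 of 14 higher and 5 adjusted over the list alone (adjusted p = 0.624 with an estimated correlation). Tendon markers had a median of 0.78 with 1 of 12 higher and 4 adjusted over the list alone (adjusted p = 0.738 with an estimated correlation). Heat shock genes had 8 of 22 higher, also adjusted over the list alone, and a median of 0.16 (adjusted p = 0.653 with an estimated correlation and 0.0626 in the paired fit).

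Oxidative phosphorylation genes passed as higher with a median of 0.14 and 1 of 28 higher, also adjusted over the list alone (adjusted p = 0.898 with an estimated correlation), and lost the call without mouse TAL341 (0.304), mouse TAL342 (0.662) or contralateral leg TAR340 (0.0567). Inflammatory cytokines passed as higher with 2 of 13 higher, 3 adjusted over the list alone and a median of 0.43 (adjusted p = 0.807 with an estimated correlation and 0.191 in the paired fit). Of the 13 cytokine genes 8 had a mean of 1 CPM or more in contralateral legs. Their call ended without mouse TAL340 (0.189) or TAL342 (0.0524) and without contralateral legs TAR344, TAR345 or TAR349 (0.052, 0.0752 and 0.0523). Passing in the paired fit alone were slow and oxidative fibre genes as higher (adjusted p = 0.0391) and endothelial (0.00942) and adipocyte markers (0.0281) as lower. The fast myosin gene Myh1 stood at 0.95 ± 0.21 (adjusted p = 0.011), at 0.0596 in the paired fit and at 0.0798 and 0.0765 without mice TAL340 and TAL341. Myh4, the fastest myosin heavy chain, stood at -0.39 ± 0.20 (adjusted p = 0.301). Myostatin (Mstn), which restrains muscle growth, stood at -0.71 ± 0.14 (adjusted p = 0.0046, paired 0.0911, without mouse TAL342 0.0656).

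After 10 days 754 genes were called, 492 higher (65.3 percent) and 262 lower, and 214 rose and 39 fell by at least 2-fold. With mitochondrial genes left out, chosen after seeing the data, 54.2 percent were higher (462 higher and 390 lower). The count was 476 without mouse TAL340, 439 without mouse TAL341, 365 without mouse TAL342 and 400 in the paired fit.

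After over 17 days of training, extracellular matrix genes rose as a group beside the early response (adjusted p = 0.463 with an estimated correlation). All 28 matrix genes were higher adjusted over the list alone and 21 of 28 over all genes tested, with a median of 1.53 and own-leg medians of 2.7, 1.3 and 0.59 in mice TAL337, TAL343 and TAL349. Col4a1, a basement membrane collagen, rose from 107 ± 25.8 CPM (SD, n = 9) to 244 ± 39.4 CPM (SD, n = 3), a log2 change of 1.21 ± 0.17 (limma adjusted p = 3.11e-04), and Lum, a proteoglycan that organises collagen fibrils, rose by 1.63 ± 0.31. Fosb rose by 5.71 ± 0.45, Egr1 by 4.90 ± 0.47 and Irs2 by 3.05 ± 0.20. Prnd, a relative of the prion protein gene, rose from 0.66 ± 0.50 to 7.21 ± 0.41 CPM. Myostatin (chromosome 1, 53100799 to 53107238) fell from 41.1 ± 5.61 to 21.8 ± 2.82 CPM, with a log2 change of -0.90 ± 0.14 (adjusted p = 6.17e-04), and Mylk2, the myosin light chain kinase of skeletal muscle, had a log2 change of -0.99 ± 0.16. Ighm dropped to 5.18 ± 1.82 CPM.

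Immediate early genes rose in this group as well (20 of 28 higher, 24 adjusted over the list alone, median 1.41, adjusted p = 0.158 with an estimated correlation). Stretch and load genes did as well (10 of 19 higher, 14 adjusted over the list alone, median 1.00, adjusted p = 0.158 with an estimated correlation). Fast glycolytic fibre genes fell, with 8 of 22 lower, 13 adjusted over the list alone and a median of -0.39 (adjusted p = 0.548 with an estimated correlation). Their own-leg medians were smaller, at -0.23, -0.28 and -0.10 in mice TAL337, TAL343 and TAL349, with 9 of 22 members above 0 in each. The fast myosin Myh4 stood at 31990 ± 1510 CPM against 57230 ± 11200 CPM, a log2 change of -0.82 ± 0.20 (adjusted p = 0.0141), with 0.189 in the paired fit and 0.0713 without mouse TAL337. Macrophage markers had a median of 1.33 with 4 of 20 higher and 16 adjusted over the list alone (adjusted p = 0.653 with an estimated correlation), and own-leg medians of 2.81, 1.51 and 0.63. Fibroblast markers had a median of 0.72 with 5 of 14 higher and 8 adjusted over the list alone (adjusted p = 0.619 with an estimated correlation). The macrophage gene Cd68 stood at 2.01 ± 0.50 (adjusted p = 0.0158), and at 1.15 without mouse TAL337 (0.166). Proliferation genes passed as higher with 4 of 11 higher and 2 lower, 8 and 2 adjusted over the list alone and a median of 0.67 (adjusted p = 0.645 with an estimated correlation and 0.0877 in the paired fit). Of these 11 genes 2 had a mean of 1 CPM or more in contralateral legs, so the filter could favour a rise. Tendon markers passed as higher with 1 of 12 higher, also adjusted over the list alone, and a median of 0.70 (adjusted p = 0.8 with an estimated correlation and 0.0786 in the paired fit), and lost the call without mouse TAL343 (0.0835) or contralateral leg TAR344 (0.0506). In the paired fit slow fibre (0.0384), cytokine (0.0144), oxidative phosphorylation (0.00231) and endothelial genes (0.0043) also passed as higher.

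After over 17 days 1197 genes were called, 859 higher (71.8 percent) and 338 lower, and 305 rose and 54 fell by at least 2-fold. After rescaling 58.6 percent were higher (917 higher and 649 lower), and with mitochondrial genes left out, chosen after seeing the data, 81.5 percent (1358 higher and 309 lower). The count was 564 without mouse TAL337. In none of the 3 mouse groups did satellite cell, atrophy and autophagy, ATF4, circadian, erythroid, adipocyte, neutrophil or PGC-1 lists pass the unpaired test. Their medians after over 17 days were 0.17, 0.00, 0.02, 0.01, 0.36, -0.23, -0.22 and -0.04.

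**Figure D2:**
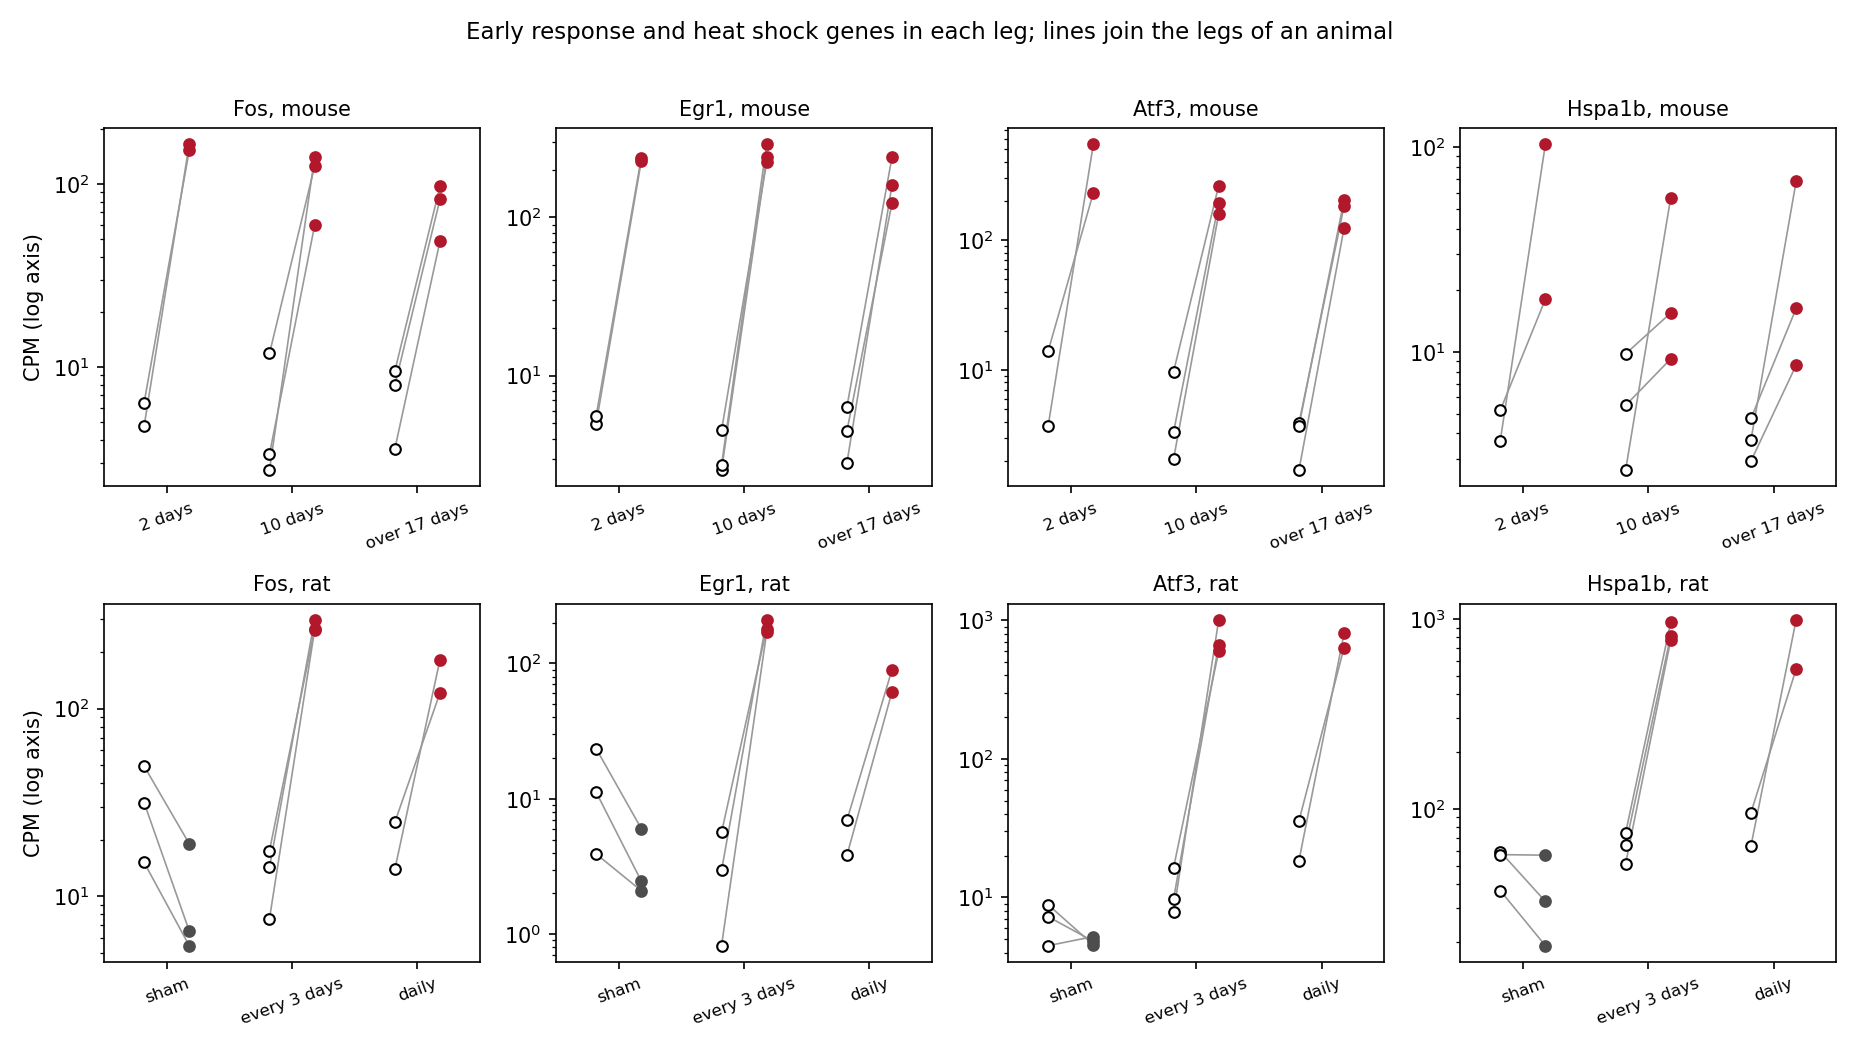
CPM on a log axis of Fos, Egr1, Atf3 and Hspa1b in each leg of mice (top) and rats (bottom), with open circles for contralateral legs, filled circles for the left leg and lines joining the legs of an animal. In every trained animal the 4 genes were higher in the stimulated leg.

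Between training lengths in mice few genes were called. After 10 against 2 days Myl12a, a regulatory myosin light chain, was lower at 193 ± 57.7 CPM (SD, n = 3) against 914 ± 609 CPM (SD, n = 2), a log2 change of -2.1 ± 0.31 (limma adjusted p = 0.032), with -1.37 without mouse TAL344 and -2.84 without mouse TAL345. The tubulin gene Tubb4b (-1.11 ± 0.18) and the adhesion receptor gene Pvr (-0.97 ± 0.16) were the other 2 of 3 called genes. In the order named, the adjusted p-values were 0.608, 0.608 and 0.666 in the paired fit, 0.2, 0.477 and 0.477 without mouse TAL344 and 0.0991 for each without mouse TAL342. Without mouse TAL341 those of Myl12a and Pvr were 0.0668 and 0.182. Rescaling gave 12 calls, 3 higher and 9 lower (25 percent higher against 0 percent), and leaving out mitochondrial genes, chosen after seeing the data, gave 11, 1 higher and 10 lower. Without mouse TAL345 the count was 1614, without mouse TAL344 it was 5, without mouse TAL340 it was 25 and without mouse TAL342 it was 0.

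After over 17 against 2 days, the lists of stretch and load genes and of heat shock genes were lower and that of endothelial markers was higher (adjusted p = 0.405, 0.548 and 0.449 with an estimated correlation). The small heat shock protein gene Cryab was lower at 534 ± 53.4 CPM (SD, n = 3) against 2091 ± 289 CPM (SD, n = 2), a log2 change of -1.97 ± 0.29 (limma adjusted p = 0.00406), and kept its call in every alternative. Csrp3 was lower by a log2 change of -3.94 ± 0.60 (adjusted p = 0.00406, paired 0.123). Prnd (2.01 ± 0.40), the vascular peptide gene Apln (1.60 ± 0.28), the endothelial receptor gene Cd93 (1.13 ± 0.20), the protease gene Adamts9 (1.79 ± 0.35) and Rapgef5 (1.12 ± 0.24) were the 5 largest rises, with paired adjusted p-values of 0.285, 0.238, 0.433, 0.27 and 0.604. In that order their adjusted p-values were 0.629, 0.414, 0.45, 0.414 and 0.909 without mouse TAL344 and 0.101, 0.0687, 0.0663, 0.0761 and 0.104 without mouse TAL343. Without mouse TAL337 those of Prnd, Cd93, Adamts9 and Rapgef5 were 0.065, 0.0555, 0.074 and 0.074, and without mouse TAL349 those of Prnd and Rapgef5 were 0.0676 and 0.102. Of 80 called genes 15 were higher (18.8 percent) and 65 lower, and after rescaling 38 were higher and 91 lower (29.5 percent). With mitochondrial genes left out, chosen after seeing the data, 46 were higher and 48 lower (48.9 percent). The count was 15 without mouse TAL344, 2236 without mouse TAL345, 38 without mouse TAL337, 18 without mouse TAL343, 37 without mouse TAL349 and 1 in the paired fit.

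Between over 17 and 10 days limma called 0 genes, with 782 at an unadjusted p under 0.05. Fast glycolytic fibre genes fell as a list, with a median of -0.25 and 0 of 22 called, also adjusted over the list alone (adjusted p = 0.488 with an estimated correlation), and this call was kept without any one library. It compares left legs of different mice and does not use their own contralateral legs. The other 10 lists called here lost the call without at least 1 library, as did 14 of 15 lists between 10 and 2 days and 9 of 13 between over 17 and 2 days. The list kept between 10 and 2 days was ribosome biogenesis, lower with a median of -0.28 and 0 of 28 called, also adjusted over the list alone (adjusted p = 0.574 with an estimated correlation). Between over 17 and 2 days 4 lists kept their call. Endothelial markers were higher with a median of 0.54 and 0 of 15 called but 10 adjusted over the list alone (adjusted p = 0.449 with an estimated correlation). Heat shock genes were lower with a median of -0.36 and 3 of 22 called and 6 adjusted over the list alone (adjusted p = 0.548 with an estimated correlation). Stretch and load genes were lower with a median of -0.70 and 4 of 19 called and 9 adjusted over the list alone (adjusted p = 0.405 with an estimated correlation). Ribosome biogenesis genes were lower with a median of -0.33 and 0 of 28 called but 2 adjusted over the list alone (0.488 with an estimated correlation).

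In rats trained daily for 30 days the fastest myosin fell and the early response was high, although its list call did not hold with an estimated correlation. Myh4, which encodes the myosin heavy chain of the fastest fibres (chromosome 10, 51923359 to 51946297), went from 62470 ± 12000 CPM (SD, n = 8) in contralateral legs to 330 ± 366 CPM (SD, n = 2), a log2 change of -8.22 ± 0.59 (limma adjusted p = 1.25e-07). It was -6.70 without rat TAL292 and -9.74 without rat TAL294. Myh1, the heavy chain of the next fastest fibres (chromosome 10, 51885913 to 51909699), stood at 50450 ± 2720 CPM against 17990 ± 6460 CPM, a log2 change of 1.57 ± 0.33 (adjusted p = 0.006), which lost its call without rat TAL292 (0.107) or TAL294 (0.0669). Other fast-fibre genes fell with Myh4, with the calcium buffer gene Pvalb at -2.86 ± 0.34, the Z-disc gene Actn3 at -2.44 ± 0.25 and Mylk2 at -1.80 ± 0.18. Ppargc1a, a coactivator that drives mitochondrial genes, rose from 11.6 ± 2.46 to 73.4 ± 1.03 CPM, and Hk2, the hexokinase of muscle, from 102 ± 26.2 to 476 ± 44.5 CPM. Atf3 rose by 5.93 ± 0.47 (paired 4.78), Nr4a3 by 6.22 ± 0.92 (paired 4.40) and the heat shock gene Hspa1b by 3.58 ± 0.32, while the slow myosin Myh7 stood at -0.30 ± 0.91 (adjusted p = 0.883).

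**Figure D3:**
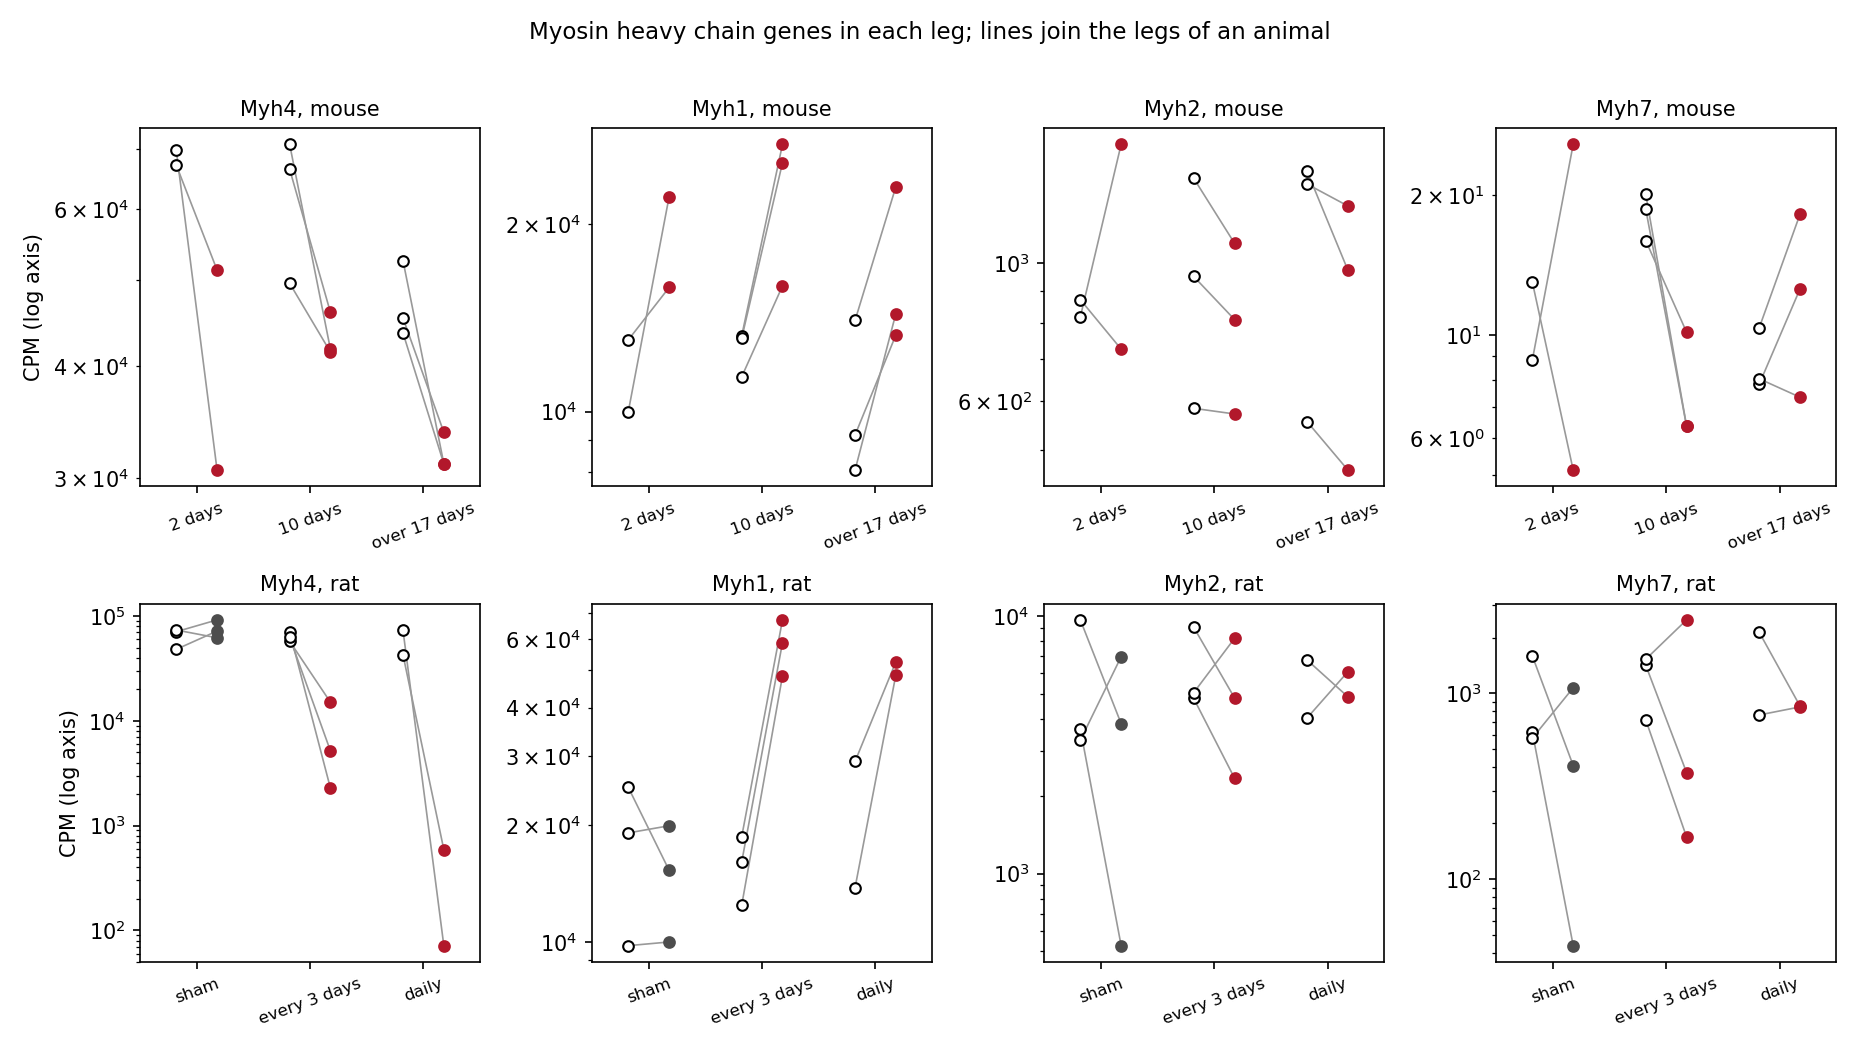
CPM on a log axis of the myosin heavy chain genes Myh4, Myh1, Myh2 and Myh7 in each leg of mice (top) and rats (bottom), with open circles for contralateral legs, filled circles for the left leg and lines joining the legs of an animal. Myh4 was lower in the stimulated leg of each of 8 mice and 5 rats, and between 71.4 and 15060 CPM in the trained rat legs against 62100 CPM or more in the sham legs.

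Under daily training 10 of 22 fast glycolytic genes fell, 11 adjusted over the list alone, with a median of -0.45 and a mean of -0.97 (adjusted p = 0.228 with an estimated correlation). Immediate early genes rose (18 of 28 higher, 20 adjusted over the list alone, median 1.72, adjusted p = 0.0573 with an estimated correlation). Stretch and load genes also rose (10 of 17 higher, 11 adjusted over the list alone, median 1.78, adjusted p = 0.191 with an estimated correlation), and heat shock genes rose too (12 of 22 higher, 13 adjusted over the list alone, median 0.86, adjusted p = 0.449 with an estimated correlation). Extracellular matrix genes rose with a median of 1.19, 8 of 24 higher and 21 adjusted over the list alone (adjusted p = 0.505 with an estimated correlation). Fibroblast markers rose with a median of 1.15, 3 of 11 higher and 8 adjusted over the list alone (adjusted p = 0.574 with an estimated correlation). Macrophage markers had a median of 0.96, 2 of 17 higher and 6 adjusted over the list alone (adjusted p = 0.727 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.39, 2 of 27 higher and 5 adjusted over the list alone, and were above 0 in 27 and 26 of 27 members in rats TAL292 and TAL294 (adjusted p = 0.663 with an estimated correlation). PGC-1 and exercise genes passed as higher with 6 of 20 higher and 1 lower, 7 and 3 adjusted over the list alone and a median of 0.34 (adjusted p = 0.695 with an estimated correlation, 0.18 in the paired fit, 0.116 without rat TAL294 and 0.0562 without contralateral leg TAR296). In the paired fit TCA cycle genes (0.0216) and adipocyte markers (0.0109) also passed as higher.

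Under daily training 851 of 10356 genes were called, 552 higher and the others lower, and 315 rose and 80 fell by at least 2-fold. The count was 123 without rat TAL292, 528 without rat TAL294, 1325 without contralateral leg TAR299 and 284 in the paired fit. Of the 49 called named genes 21 lost the call without rat TAL292, among them Fos at 2.95 ± 0.49 (0.071), Egr1 at 3.72 ± 0.66 (0.0882) and Ankrd1 at 215 ± 90.2 against 43.1 ± 22.6 CPM (0.269), whose log2 change of 2.41 was 3.14 in the paired fit.

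In rats trained every 3 days for 30 days immediate early genes rose as well, and the fastest myosin fell. Myh4 went from 62470 ± 12000 CPM (SD, n = 8) to 7499 ± 6710 CPM (SD, n = 3), a log2 change of -3.45 ± 0.50 (limma adjusted p = 2.02e-04; -2.80 without rat TAL295 and -4.16 without rat TAL298), and Myh1 from 17990 ± 6460 to 57990 ± 9470 CPM, a log2 change of 1.76 ± 0.28. Egr1 rose from 7.34 ± 7.21 to 187 ± 20.9 CPM, a log2 change of 5.03 (paired 5.94), and Atf3 (chromosome 13, 102751319 to 102764625) from 13.6 ± 10.1 to 757 ± 220 CPM. Gdf15, a secreted stress hormone, rose by 4.16 ± 0.26, the chemokine gene Ccl2, which recruits monocytes, by 3.44 ± 0.45 and Ppargc1a by 1.96 ± 0.18. The clock gene Ciart rose from 2.26 ± 2.26 to 67.2 ± 4.50 CPM. Prima1, which anchors acetylcholinesterase at membranes, fell from 22.6 ± 9.61 to 2.43 ± 0.98 CPM.

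The immediate early list rose with 20 of 28 higher, 22 adjusted over the list alone and a median of 2.31, and held with an adjusted p of 0.0241 with an estimated correlation. Heat shock genes rose with 11 of 22 higher, 12 higher and 2 lower adjusted over the list alone and a median of 0.63 (adjusted p = 0.463 with an estimated correlation), and Dnajb1, a partner of heat shock protein 70, rose by 2.43 ± 0.26. Extracellular matrix genes had a median of 0.95, 8 of 24 higher and 15 adjusted over the list alone (adjusted p = 0.519 with an estimated correlation). Stretch and load genes had a median of 1.40, 9 of 17 higher and 10 adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Inflammatory cytokines had a median of 1.13, 5 of 10 higher and 7 adjusted over the list alone (adjusted p = 0.463 with an estimated correlation). Of these 10 genes 6 had a mean of 1 CPM or more in contralateral legs. Fibroblast markers had a median of 0.71, 2 of 11 higher and 3 adjusted over the list alone (adjusted p = 0.645 with an estimated correlation). Proliferation genes had a median of 0.56, 4 of 12 higher and 1 lower, and 6 and 1 adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). Of these 12 genes 3 had a mean of 1 CPM or more in contralateral legs, so the filter could favour a rise. Fast glycolytic genes fell with a median of -0.18, 2 of 22 lower and 3 adjusted over the list alone (adjusted p = 0.548 with an estimated correlation). Macrophage markers passed as higher with a median of 0.55, 2 of 17 higher and 3 adjusted over the list alone (adjusted p = 0.785 with an estimated correlation), and lost the call without rat TAL295 (0.411). Ribosomal protein genes passed as lower with a median of -0.08, 1 of 40 lower and 0 adjusted over the list alone (adjusted p = 0.807 with an estimated correlation, 0.43 in the paired fit and 0.0641 without contralateral leg TAR296).

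Under training every 3 days 690 genes were called, 514 higher and 176 lower, and 275 rose and 25 fell by at least 2-fold. The count was 323 without rat TAL295 and 411 without rat TAL299. Of the 52 called named genes 40 kept their call in every alternative.

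**Figure D4:**
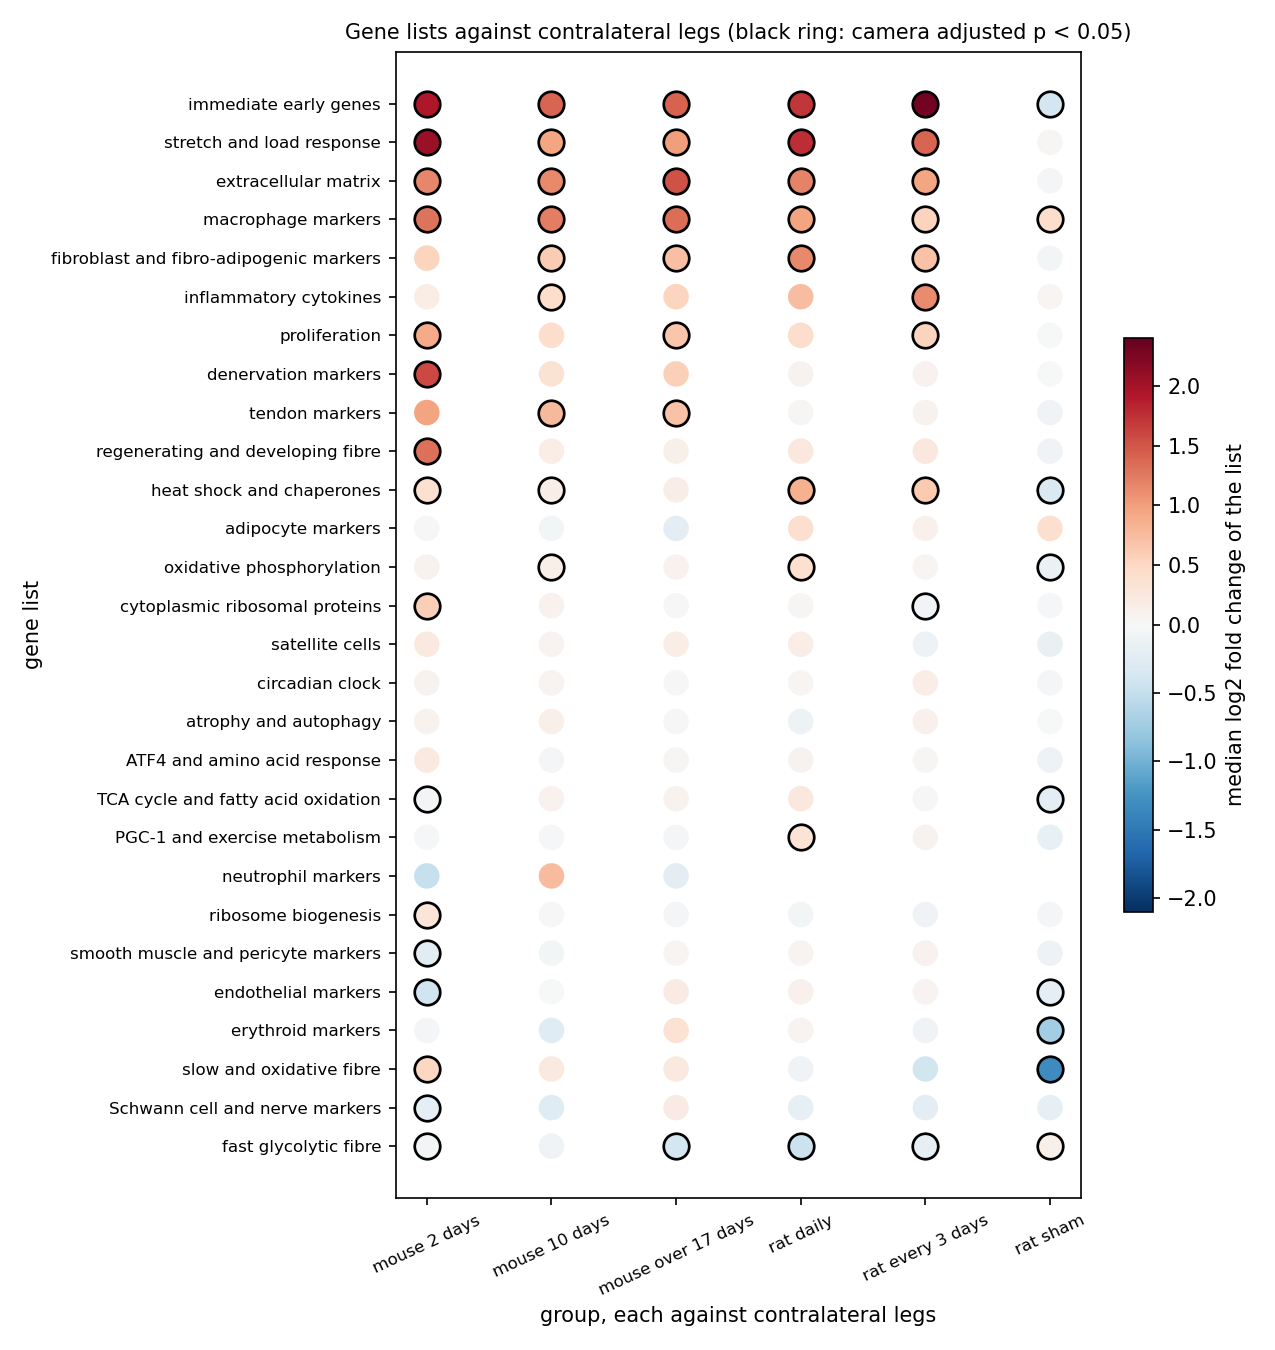
Median log2 change (colour) of each gene list (vertical axis) in each group against contralateral legs (horizontal axis), with a black ring where camera in limma called the list. Immediate early genes and stretch and load genes were called as higher in the 5 trained groups, and the median of immediate early genes was -0.39 in the sham group. With an estimated correlation only the call of immediate early genes in rats trained every 3 days held.

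Sham surgery against contralateral legs gave no called gene. Limma called 0 of 10356 genes, with 282 at an unadjusted p under 0.05, and the highest count without a library was 1, without contralateral leg TAR297. Myh4 stood at 75400 ± 15300 CPM (SD, n = 3) in sham legs and 62470 ± 12000 CPM (SD, n = 8) in contralateral legs, Atf3 at 4.86 ± 0.34 against 13.6 ± 10.1 CPM and Ppargc1a at 13.3 ± 3.16 against 11.6 ± 2.46 CPM. As lists, 9 passed with 0 members called. Slow and oxidative fibre genes had a median of -1.32 (adjusted p = 0.463 with an estimated correlation), with own-leg medians of -2.96 and -1.66 in rats TAL296 and TAL297 and 0.91 in rat TAL300. Immediate early genes had a median of -0.39 (adjusted p = 0.291 with an estimated correlation), erythroid markers -0.72 with 3 of 7 lower adjusted over the list alone (0.272 with an estimated correlation) and macrophage markers 0.43 (0.488 with an estimated correlation). Heat shock genes had a median of -0.33 with 3 of 22 lower adjusted over the list alone (adjusted p = 0.462 with an estimated correlation and 0.0524 in the paired fit). Adjusted over the list alone, 0 members of the other 7 lists were called.

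Fast glycolytic genes in sham legs had a median of 0.14 (adjusted p = 0.463 with an estimated correlation), TCA cycle genes -0.22 (0.8 with an estimated correlation), oxidative phosphorylation genes -0.14 (0.8 with an estimated correlation) and endothelial markers -0.21 (0.785 with an estimated correlation, 0.0682 in the paired fit). These 4 calls ended without sham rat TAL296, with adjusted p-values of 0.188, 0.96, 0.915 and 0.207, and that of endothelial markers also without contralateral leg TAR296 (0.198) or TAR299 (0.0588). In the paired fit ribosomal proteins (3.12e-06), fibroblast markers (0.0154), Schwann cell markers (0.0195) and extracellular matrix genes (0.0273) also passed as lower. Contralateral legs of the 5 trained rats and of the 3 sham rats were compared as well, and limma called 0 genes, with 415 at an unadjusted p under 0.05.

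Against sham legs, Atf3 and Ppargc1a rose in both rat training groups. Under daily training Myh4 was at 330 ± 366 CPM (SD, n = 2) against 75400 ± 15300 CPM (SD, n = 3), a log2 change of -8.50 ± 0.68 (limma adjusted p = 5.23e-07; -6.98 without rat TAL292 and -10.02 without rat TAL294). Atf3 rose by 7.06 ± 0.55 (paired 5.19) and Ppargc1a by 2.45 ± 0.25. Under training every 3 days Atf3 rose by 7.11 ± 0.49 (paired 6.44), Ppargc1a by 1.77 ± 0.22, Hk2 by 2.92 ± 0.23 and the angiogenic growth factor gene Vegfa by 1.96 ± 0.22. Myh4 in that group stood at -3.73 ± 0.61 (adjusted p = 8.22e-04, paired 0.0732; -3.08 without rat TAL295 and -4.44 without rat TAL298). Daily training gave 843 called genes, 573 higher (68 percent) and 270 lower, and 55.2 percent were higher after rescaling (507 higher and 412 lower). That count was 188 without rat TAL292, 517 without rat TAL294, 420 without sham rat TAL296, 426 without sham rat TAL297 and 143 in the paired fit. Training every 3 days gave 440 called genes, 368 higher and 72 lower, with 267 without rat TAL295, 272 without rat TAL299, 270 without sham rat TAL296, 250 without sham rat TAL297 and 172 in the paired fit.

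By list against sham legs, immediate early genes rose in the group trained every 3 days (20 of 28 higher, 22 adjusted over the list alone, median 2.91, holding at an adjusted p of 0.0217 with an estimated correlation). They also rose in the daily group (18 of 28, 21 adjusted over the list alone, median 2.08, adjusted p = 0.0573 with an estimated correlation). Fast glycolytic genes fell in the daily group (10 of 22 lower, 11 adjusted over the list alone, median -0.48, adjusted p = 0.158 with an estimated correlation). They also fell under training every 3 days (4 of 22 lower, 7 adjusted over the list alone, median -0.29, adjusted p = 0.272 with an estimated correlation). Oxidative phosphorylation genes rose in the daily group (4 of 27 higher, 8 adjusted over the list alone, median 0.50, adjusted p = 0.619 with an estimated correlation), and in the group trained every 3 days they had a median of 0.19 and were not called (adjusted p = 0.211). Erythroid markers passed as higher under training every 3 days (2 of 7 higher, also adjusted over the list alone, median 0.75, adjusted p = 0.645 with an estimated correlation), and lost the call without rat TAL295 (0.057) or sham rat TAL296 (0.0693). Slow fibre genes passed as higher in both groups, with medians of 1.31 (3 of 17 higher, also adjusted over the list alone) and 0.97 (1 of 17, also adjusted over the list alone), with adjusted p-values of 0.785 and 0.8 with an estimated correlation. Without sham rat TAL296 the adjusted p-values of camera at the preset correlation were 0.138 and 0.565. Under training every 3 days the adjusted p was 0.218 without rat TAL299 and 0.261 in the paired fit. Slow fibre and erythroid genes were called lower in sham legs and were not called against contralateral legs in either training group. Their rise against sham legs can thus not be told apart from low sham values. In all 10 lists were called in the daily group and 12 under training every 3 days, and the others are not described here.

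Daily training and training every 3 days were then compared directly. The fastest myosin was lower under daily training, with Myh4 at 330 ± 366 CPM (SD, n = 2) against 7499 ± 6710 CPM (SD, n = 3), a log2 change of -4.77 ± 0.68 (limma adjusted p = 0.00586, paired 0.618, and 0.185 without rat TAL292). The change was -3.25, -6.29, -5.42 and -4.06 without rats TAL292, TAL294, TAL295 and TAL298. Gdf15 was lower at 1.10 ± 0.27 against 10.0 ± 1.60 CPM (log2 -2.71 ± 0.35, adjusted p = 0.00321, paired 0.618) and Actn3 at 2258 ± 1100 against 7776 ± 1160 CPM (adjusted p = 0.0121, paired 0.713, and 0.32, 0.0531 and 0.0713 without rats TAL292, TAL295 and TAL298). Limma called 9 of 10356 genes, 0 higher and 9 lower, and 0 in the paired fit, with 609 at an unadjusted p under 0.05 in the unpaired fit. The count was 3 without rat TAL292, 14 without rat TAL294 and 4 without each of rats TAL295, TAL298 and TAL299.

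Between the frequencies 4 lists kept their call without any one library. Fast glycolytic genes were lower under daily training (2 of 22, 5 adjusted over the list alone, median -0.25, adjusted p = 0.272 with an estimated correlation). Oxidative phosphorylation genes were higher (0 of 27 called, also adjusted over the list alone, median 0.33, adjusted p = 0.488 with an estimated correlation). Immediate early genes were lower (0 of 28, 2 adjusted over the list alone, median -0.30, adjusted p = 0.548 with an estimated correlation). Circadian clock genes were lower (0 of 16, 1 adjusted over the list alone, median -0.33, adjusted p = 0.158 with an estimated correlation and 0.237 in the paired fit). The remaining 4 of 8 called lists lost the call without at least 1 library.

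**Figure D5:**
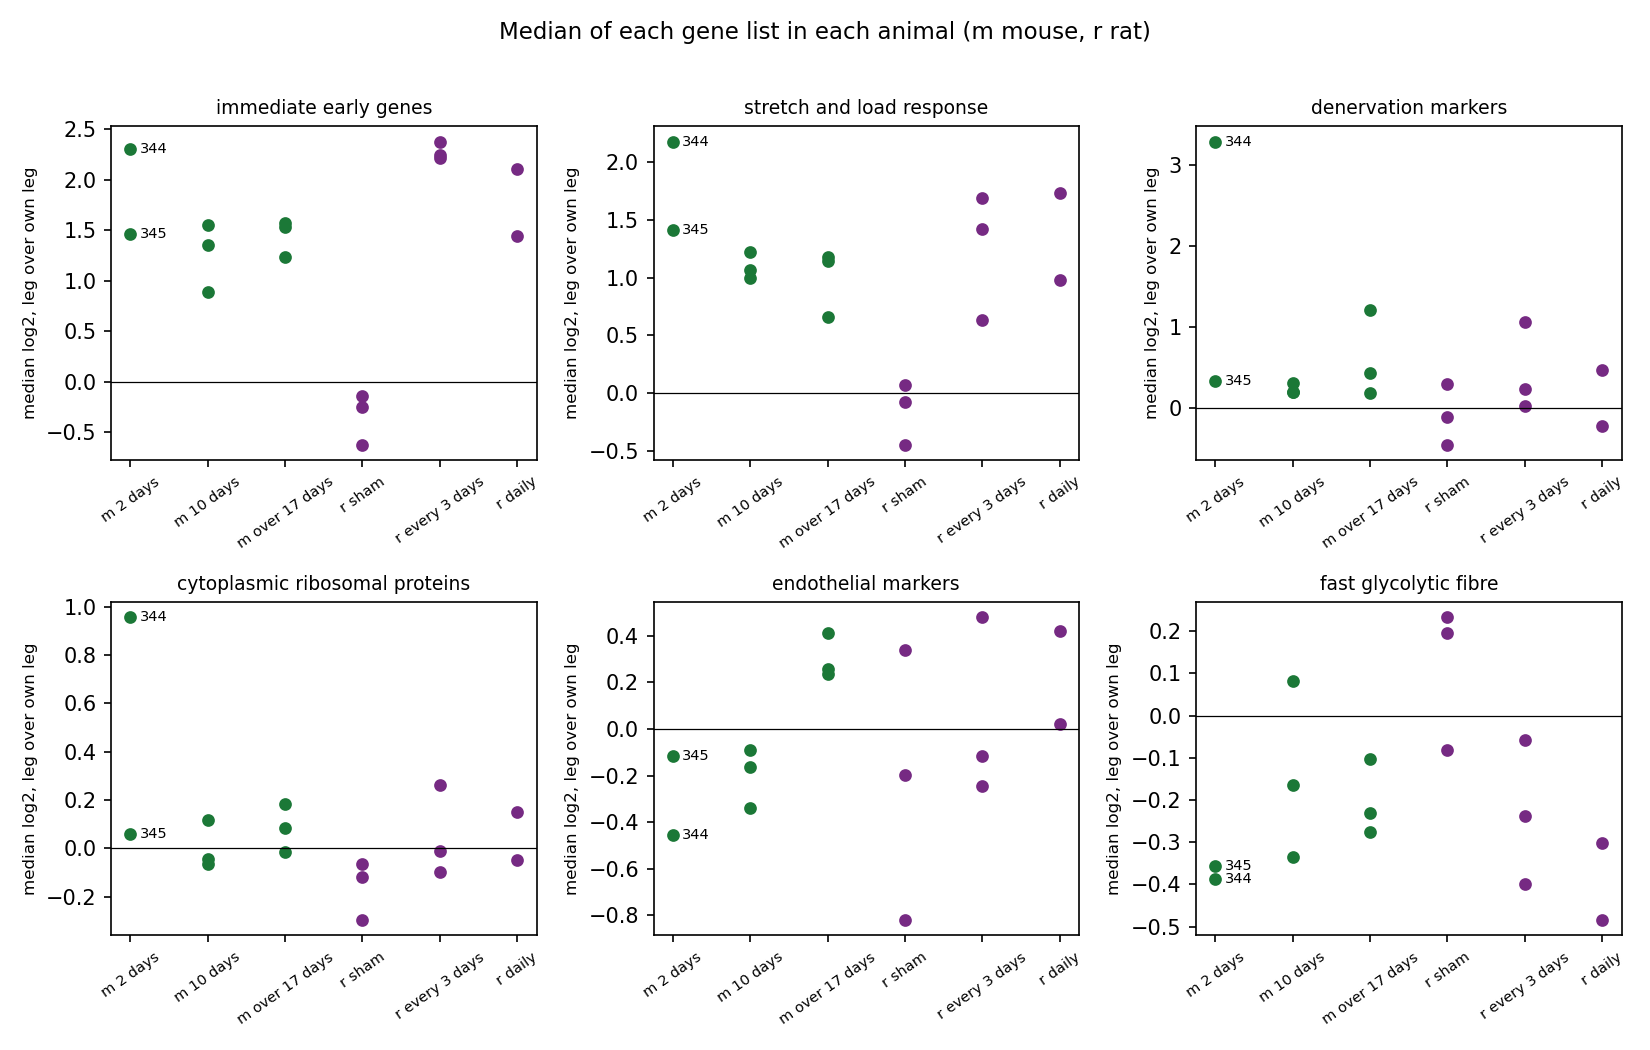
Own-leg median log2 change (vertical axis) of 6 gene lists in each animal, grouped by training (horizontal axis), with mice in green and rats in purple. Among 2-day mice, TAL344 stood at 3.29 for denervation markers and 0.96 for ribosomal proteins, and TAL345 at 0.34 and 0.06.

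The responses were also compared across groups and species. Over genes, own-leg log2 changes correlated at 0.779 between the mice of over 17 and 10 days, 0.646 between over 17 and 2 days, 0.674 between 10 and 2 days and 0.692 between the rat training groups, while the sham changes correlated at -0.188 with daily training and -0.079 with training every 3 days. Genes are not independent replicates, and these changes use each animal's own contralateral leg. Between species, the unpaired log2 changes against all contralateral legs of a species were compared over 9432 shared symbols. The mice of over 17 days correlated with daily trained rats at 0.58, with rats trained every 3 days at 0.597 and with sham rats at -0.033. The mice of 2 days correlated with the rat training groups at 0.431 and 0.44 and those of 10 days at 0.519 and 0.571. Between single animals, own-leg changes of the mice of over 17 days correlated with daily trained rats at 0.382 to 0.462. They correlated with rats trained every 3 days at 0.211 to 0.558 and with sham rats at -0.168 to 0.081. Of the called genes in the pair of groups with the highest correlation, 224 were higher in the mice of over 17 days and in rats trained every 3 days, against 33.1 by independent lists, 26 were lower in both (4 by independent lists) and 4 went in opposite directions. Across the 5 trained groups 94 genes were higher in each and 9 lower in each, against 6 and 0.5 by independent lists of the species. In 20 simulations of unchanged groups with the same controls the count was at most 0. The simulations drew each gene independently, with no shift shared within a library or an animal, so they say nothing about such shifts. The comparisons within a species shared their contralateral legs, and the chance values for the 5 groups take the genes shared within each species as given. Atf3, Nr4a3, Fosb, Egr1, Fos, Csrnp1, Irs2 and Mustn1 led the shared rises by mean log2 change, and the 9 shared falls were Wnt4, Tpx2, Adhfe1, Gpt2, Mylk2, Gdpd5, Sumf2, Zfp870 and Me1, all chosen after their values were seen.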

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

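The tests of the myosin pattern in this part were chosen only after the result was seen. Mouse TAL344 and the myosin pattern were taken up outside any fixed measure. The other genes, legs and differences below were picked by 2 fixed measures, the gap of a contralateral leg to its nearest neighbour over the range of the group, and a tested difference between groups. Such a gap exceeds its limit in about 5 percent of genes by chance, and it did so in 10 of 124 mouse genes and 7 of 95 rat genes.

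Mouse contralateral leg TAR340 stood far above the other 8 in the chemokine gene Ccl7 (gap over range 0.639), the macrophage gene Cd68 (0.647, with 5.15 CPM against 0.645 to 1.51), the growth gene Myc (0.505), the muscle differentiation factor Myog (0.62, with 8.34 against 1.23 to 2.71 CPM) and the matrix regulator Timp1 (0.616). Other mouse contralateral legs far from the rest were TAR345 in the muscle LIM gene Lmcd1 (0.675) and TAR337 in the proliferation gene Top2a (0.606). In rats, contralateral leg TAR300 stood apart in Chrna1 (0.721, with 18.9 against 3.49 to 5.71 CPM) and as the lowest in the chaperone gene Hsp90aa1 (0.57) and the cytokine inhibitor Socs3 (0.56). Leg TAR299, of the lowest depth, stood apart in Gdf15 (0.85, with 0.616 against 0 to 0.0642 CPM) and Pvalb (0.605, with 4020 against 997 to 1730 CPM). Leg TAR294 did so in the phosphatase gene Dusp2 (0.632, with 0.806 against 0.205 to 0.385 CPM) and leg TAR292 as the lowest in Snai3 (0.591). Some of these genes lay near the floor, among them Gdf15, Dusp2, Socs3 (0.264 against 0.806 to 1.49 CPM) and mouse Ccl7 (0.994 against 0.0958 to 0.33 CPM). A single read in leg TAR299 was worth 0.205 CPM, so the gap of Gdf15 was a few reads.

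Groups differed by tests of the difference itself in limma, with 3 genes called between mice trained for 10 and 2 days, 80 between over 17 and 2 days, 9 between rats trained daily and every 3 days, 843 between daily and sham rats and 440 between rats trained every 3 days and sham rats. The report gives how these counts moved without single libraries.

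The response of 2-day mouse TAL344 stood apart from that of mouse TAL345. After median-of-ratios rescaling the own-leg median of ribosomal proteins in mouse TAL344 was 0.676, against -0.087 to 0.125 in the other trained mice (SD 0.076), so scaling of the CPM is argued against. A lower share of muscle RNA, with all other cell types gaining alike, would raise the markers of each of them. The endothelial markers, 15 of 15 expressed in contralateral legs, had a median of -0.453 (SD 0.273 over the other trained mice). Macrophage and fibroblast markers had 2.35 and 0.87. This argues against an even gain only, and a lower share of muscle RNA with an uneven gain of other cells is not excluded. An exchange of the legs of mouse TAL345 is argued against by its own-leg median of immediate early genes, 1.47 (SD 0.318). A stronger reaction of this animal to the implant or to training stays open, and no biological explanation was tested.

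In mouse contralateral leg TAR348, from the animal without a left leg here, Egr1 (gap over range 0.652, with 31.0 against 2.54 to 6.35 CPM), Fos (0.575, with 75.1 against 2.74 to 11.9 CPM) and Fosb (0.713, with 4.32 CPM) were the highest of the contralateral legs. A stimulated leg with a contralateral label is argued against, since the stretch and load list of leg TAR348 stood 0.054 from the other contralateral legs and 0.813 to 2.20 in the stimulated legs (SD 0.254). After rescaling the gap of Fos was 0.605, still above its limit, which argues against scaling of the CPM. What handling or time of sampling did to this leg stays open, and no biological explanation was tested.

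Myh4 fell and Myh1 rose in the stimulated rat legs. Reads moved between near-identical myosin genes would leave other fast-fibre genes unchanged. The median of 18 fast glycolytic genes, without Myh4, the light chain genes Myl1 and Mylpf and the kinase gene Mylk2, was -0.453 under daily training. It was -0.183 under training every 3 days, with an SD of this median over the contralateral legs of 0.097. These falls do not measure how reads were divided among the myosin genes. The side of the body, surgery or dissection would lower Myh4 in sham legs, where the lowest value was 62100 CPM (SD 15270), against 71.4 to 15060 CPM in the stimulated legs. Myh4 was a fixed gene, and its fall was called against contralateral legs in both rat training groups. That training caused the fall is left as a hypothesis, since the explanations were tested on the same data after it was seen. No test separated a switch of fibres away from the fastest type from changed transcription in existing fibres, both of which stay open, and the split of reads among the myosin genes keeps their separate levels uncertain.

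Other splits of the same libraries were counted for the comparisons with at least 3 samples in each group. Over splits that ignore which legs share an animal, only the real one of 100 gave as many as the 754 genes after 10 days (highest other 1). The same held for the 1197 genes after over 17 days (1 of 100, highest other 1). It also held for the 690 genes under training every 3 days (1 of 100, highest other 8). Since the legs are paired by animal, these splits are not equally likely by chance, so they do not exclude it. The splits that part as many pairs of legs number 8 in each case, too few for a share under 0.05, and gave at most 5, 1 and 0 genes besides the real ones. For the 440 genes between training every 3 days and sham (1 of 10 splits, highest other 0), 10 splits are too few for a share under 0.05.

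Where limma called 0 genes every split gives as many by construction, so the splits say nothing about chance. This covers over 17 against 10 days (10 of 10 splits, highest other 2, 782 genes at an unadjusted p under 0.05), sham against contralateral legs (100 of 100 splits, 282 at an unadjusted p under 0.05) and contralateral legs of trained against those of sham rats (56 of 56 splits, highest other 1, 415 at an unadjusted p under 0.05). For sham against contralateral legs another split gave 206 genes, which points to a structure of the samples that was not identified, while the splits parting as many pairs gave at most 0.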

How the results depend on the processing

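The tests without mouse mitochondrial genes, without rat ribosomal RNA, with rat transcript models not summed and with each library left out of the lists were chosen only after the result was seen, and the other alternatives before the data were examined. Of the 439 values of named genes 429 kept direction and call after rescaling, 435 with a pseudocount of 2, 420 without a filter, 399 with only the 2 groups compared, 432 with the animal as a random effect and 347 with the animal as a block. Of 4320 values with 1 library left out 3950 did. Direction and call were also kept by 207 of 214 values without mitochondrial genes, 222 of 225 without ribosomal RNA and 212 of 214 without summing. Of the 370 called values a pseudocount of 2 moved the fold of 61 by over 1.5 times, each toward 0. The animal as a block did so for 39, of which 25 went toward 0, and leaving out 1 library did so for 49, in 90 fits, of which 49 went toward 0.

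Counts of called genes moved by over 1.5 times as follows, and the cause was not tested. A pseudocount of 2 gave 5 genes for 10 against 2 days and 2 for over 17 against 10 days. No filter gave 14 for 10 against 2 days, rescaling gave 12 for it and 129 for over 17 against 2 days, and leaving out mitochondrial genes gave 11 for 10 against 2 days. Only the 2 groups compared gave 1250 for 10 days, 0 for 10 against 2 days, 4 for over 17 against 2 days and 21 for daily against every 3 days. Without ribosomal RNA that last comparison gave 5. The animal as a block gave 560 for 2 days, 400 for 10 days, 1 for 10 against 2 days, 1 for over 17 against 2 days, 284 for daily training, 0 for daily against every 3 days, 143 for daily against sham and 172 for every 3 days against sham. With the block 89 calls of named genes ended and 3 were gained, and it moved no other count by over 1.5 times.

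Leaving out 1 library in turn gave 196 (mouse TAL344) to 3421 genes (mouse TAL345) for 2 days, 365 to 978 for 10 days, 564 to 1449 for over 17 days, 0 to 1614 for 10 against 2 days, 0 to 0 for over 17 against 10 days and 15 to 2236 for over 17 against 2 days. In rats it gave 123 to 1325 for daily training, 323 to 983 for every 3 days, 0 to 1 for sham, 3 to 14 for daily against every 3 days, 188 to 899 for daily against sham and 250 to 471 for every 3 days against sham. Chrna1 after 2 days reversed without mouse TAL344, at -0.086, and reached 4.88 without mouse TAL345. Where 1 sample was left it was assumed to vary like the other groups.

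Of 130 list calls 2 held with an estimated correlation. By fry, which does not compare a list with other genes, 86 of the 130 did not pass and 11 other lists did, which made 55 in all, and this says nothing about a difference from other genes. With the animal as a block 6 lists reversed, and the cause was not tested: macrophage (adjusted p = 0.00646) and neutrophil markers (0.55) between 10 and 2 days, neutrophil markers between over 17 and 10 days (0.301), fast glycolytic genes between over 17 and 2 days (0.000138), extracellular matrix genes in sham legs (0.0273) and ribosomal proteins between every 3 days and sham (0.318). All but the matrix genes in sham legs are between groups of left legs. There the block compares own-leg changes and not the left legs themselves, so the 2 fits measure different quantities. The planned count tests were not run, since whole reads were not recovered. At 4.9 M reads in rat contralateral leg TAR299, 1 read was worth more CPM than in any other library, which limits low genes there.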

Other observations

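The tests of the polyamine genes and of Ighm, Igkc and Ptprc were chosen only after the result was seen. The prediction for the load hypothesis was written before its test. Among 7 genes of polyamine metabolism, which were not tested as a list, some were called in stimulated muscle and others were not. Sat1, which acetylates polyamines for export, rose by 1.33 ± 0.20, 0.83 ± 0.17 and 1.11 ± 0.17 on the log2 scale after 2, 10 and over 17 days in mice. In rats trained daily and every 3 days it rose by 1.49 ± 0.26 and 1.29 ± 0.22. The limma adjusted p-values in that order were 4.62e-04, 0.00752, 5.99e-04, 0.00138 and 0.00124, with 0.0813 after 10 days without mouse TAL340 and 0.119 under daily training without rat TAL292. Amd1, which makes the donor for spermidine synthesis, stood at 810 CPM in mouse contralateral legs and at 222, 224 and 215 CPM in the stimulated legs. Its 2-day log2 change of -2.11 became -1.22 without mouse TAL344 (adjusted p = 0.0587), and in rats its log2 changes were -0.31 (0.253) and -0.27 (0.287). Reads of its copies Amd2 and Amd-ps3 make the level of Amd1 uncertain. These copies also fell, by log2 changes of -2.13 and -1.96 after 2 days (-1.39 and -1.28 without mouse TAL344). After over 17 days they stood at -2.11 to -1.79 and -2.39 to -1.72 over the left-out libraries. This argues against a move of reads among the 3 as the source of the fall in these groups. Azin1, which frees ornithine decarboxylase from its inhibitor, rose by 1.33 ± 0.20, 0.92 ± 0.17 and 1.08 ± 0.17 in mice. In rats it stood at 0.66 (adjusted p = 0.0561, and 0.0384 without contralateral leg TAR292) and 0.49 (0.115, paired 0.0317).

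Smox, which oxidises spermine, was called lower in the 3 mouse groups at -1.45, -1.10 and -1.28, but each call ended in some setting. After 2 days it was -0.82 without mouse TAL344 (adjusted p = 0.611). After 10 days the adjusted p was 0.117 in the paired fit, 0.26 without mouse TAL340 and 0.0509 to 0.0814 without any one of TAL341, TAL342, TAR341, TAR342, TAR344, TAR345, TAR348 or TAR349. After over 17 days it was 0.0857 in the paired fit and 0.118 without mouse TAL337. In rats Smox stood at -1.01 under daily training (adjusted p = 0.0073, paired 0.0647, and 0.108 and 0.086 without rats TAL292 and TAL294) and at -0.52 under training every 3 days (0.11, paired 0.0366). Odc1, the ornithine decarboxylase gene, stood in mice at 0.75 (0.123 without mouse TAL344), 0.46 (paired 0.264, and 0.153 and 0.102 without mice TAL341 and TAL342) and 0.02 (adjusted p = 0.943). The spermidine synthase gene Srm stood at 0.87 after 2 days (paired 0.0759, and 0.42 without mouse TAL344), 0.36 (0.344) and 0.08 (0.856), and the spermine synthase gene Sms was not called in mice (0.418, 0.89 and 0.441). In rats Odc1 (0.605 and 0.883), Srm (0.15 and 0.0809) and Sms (0.702 and 0.595) were not called, but Srm was called lower without contralateral leg TAR299 (0.0439 and 0.0152) and, under training every 3 days, in the paired fit (0.0165).

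Ighm, which encodes the constant region of IgM, stood at 54.8 CPM in mouse contralateral legs and at 22.2, 6.88 and 5.18 CPM in stimulated legs after 2, 10 and over 17 days. The 2-day value lost its call without mouse TAL344 (limma adjusted p = 0.261 against 0.00468). Igkc, the kappa light chain gene, had log2 changes of 0.01, 0.81 and 0.42 (adjusted p = 0.996, 0.475 and 0.705), and Ptprc, a gene of all white blood cells, 0.73, 1.05 and 1.26 (0.483, 0.303 and 0.162).

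The stretch and load list was highest after 2 days, with own-leg medians of 2.18 and 1.41 in the 2 mice and at most 1.22 in the 6 mice trained longer. A load response that declines with repeated training may explain this, and an exact permutation test gave a 2-sided p of 0.0357, the smallest that the 28 splits can give. With both 2-day mice highest, this is the p that the pattern itself gives, so it adds no support of its own. Mouse TAL344 stood apart in other lists as well, and different mice were used at each length, so differences between animals stay open. An effect of the implant surgery stays open too, since no mouse leg was sham-operated.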
